A study of Homo sapiens with 22 samples.

How the data were processed

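ATAC-seq peak lists were analysed for 22 libraries of the multiple myeloma cell lines KMS11 (12 libraries) and KMS34 (10 libraries). The labels give the genotype t(4;14) for every library except a pair of KMS11 libraries labelled TKO, a label whose meaning is not given in the sources used here. The 11 groups hold 2 libraries each: KMS11 and KMS34 at day 0, both lines in DMSO and in NSD2LDD at day 4 and at day 10, and KMS11 TKO at day 0. The titles number the libraries of a group as duplicates, and nothing says whether these are separate cultures, so the p-values measure only the spread between these samples. Concentrations of NSD2LDD are not given in the sources used here.

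Per the labels, the reads were processed with fastp, BWA, SAMtools, Picard, MACS3 and deepTools on hg38, and peaks were called in each library separately. Versions, the Tn5 shift, duplicate removal and the calling settings are not given in the sources used here. The deposited score of a peak is 10 times its -log10 q as a whole number, and the deposited fold enrichment is a ratio over the background the caller modelled in that library. The deposited -log10 q of each peak was used only to rank or filter peaks within a list, and the smallest -log10 q in the lists is 2.00. The deposited -log10 p, the score and the ratio were not used. The lists hold no read counts, so the depth of each library is unknown and a peak that is not called cannot be told from one too shallow to call. The peak lists held 24979 to 52518 peaks (median 37598.5), and list length was used in place of depth in the alternatives.

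Peaks on the 22 autosomes and X were merged across libraries into 96166 regions. The computation of covered bases was checked against bedtools 2.31.1 on simulated intervals. The value of a region in a library was the number of its bases covered by peaks called in that library, and the value of a gene was the covered length within its body and 5 kb either side. Gene positions came from a RefSeq annotation of GRCh38.p14 that holds 19974 protein-coding genes on these chromosomes. It gives no strand, exons or sequence, so transcription start sites, exons, motifs and GC content were not analysed here, and windows of 1 kb around both gene ends stand in place of promoters. Regions called in at least 2 libraries (69187) and genes covered in at least 2 libraries (16738) were tested. Values were log2 of the covered length plus 100 bp for regions or 200 bp for genes, less the library median over the features called in all libraries (13884 regions).

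Differences were fitted with limma 3.58.1 (trend and robust) in R 4.3.3, with 1 mean for each of the 11 groups over all 22 libraries and Benjamini-Hochberg adjustment at 0.05. The comparisons were NSD2LDD minus DMSO in each line over both days (4 libraries against 4), the difference of these effects between lines, TKO minus day 0 KMS11 (2 against 2), and KMS34 minus KMS11 over day 0 and DMSO libraries (6 against 6). Values per library (peak number, shares of peaks by class, list means, shares of regions called) were compared by exact permutation of the NSD2LDD and DMSO labels within line and day, or within 1 line ignoring day, where the 70 relabellings give a two-sided p of 0.0286 at the lowest. For 2 libraries against 2 the lowest exact p is 0.333, so no such p is given. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

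Before the data were examined, the groups, comparisons, alternatives, 17 gene lists and the rule for named genes were fixed. The rule names, among called features, the 10 largest falls and 10 largest rises for genes and the 5 largest of each for regions (under NSD2LDD those that moved the same way at both days), the 4 called members of each list with the smallest p, and always NSD2, FGFR3, MYC, CCND2, IRF4 and MAF. The lists cover genes tied to t(4;14) and NSD2, plasma cells, B cells, AP-1 and MAPK signalling, NF-kappaB, interferon response, antigen presentation, adhesion, cell cycle, apoptosis, writers and erasers of H3K36 and H3K27 methylation, developmental regulators, housekeeping, and markers of T and NK, myeloid, erythroid and megakaryocyte, and stromal and endothelial cells. For each list the count of called genes is given over all genes and adjusted over the list alone. Where a group had no called peak, a fold is mostly not given, because the log2 difference then depends on the bases added. Exceptions are the differences between lines at DCLK2, NTRK2 and SORCS3 and some values at gene ends.

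The alternatives were peaks with -log10 q of 5 or more, lists shortened to their 24979 strongest peaks, no scaling, quantile normalization, log2 peak number as a covariate, a fit within 1 line, replicate number as a block, limma without trend and robust, other bases added (30 and 300 bp for regions, 50 and 1000 bp for genes), other minimums of libraries, windows around peak summits, called or not in place of covered length, 50 kb either side of gene ends, gene ends alone, and leaving out each library in turn. The windows of 50 kb either side lay around both gene ends in place of the gene body. They leave out the middle of long genes. The procedure was tested on simulated data in which 100 features were shifted by 1 or 2 on the log2 scale. For genes 61% and 90% were recovered in the TKO comparison, 77% and 96% under NSD2LDD in KMS11, 77% and 98% in KMS34 and 88% and 98% between lines. For regions these shares were 25% and 53%, 40% and 72%, 28% and 61%, and 38% and 62%. False calls numbered 0 to 9 for genes and 0 to 4 for regions. The shifted features were widely covered ones, the shifts had no floor at no called peak, and the simulated days did not differ. These shares and false calls therefore do not cover peaks called in 1 group alone or differences between days. Reads were not used here, and the other data types named in the series design were not analysed here. Results of some named genes are not reported here.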

Results

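KMS11 and KMS34 are multiple myeloma cell lines with the t(4;14) translocation. It places NSD2, a histone methyltransferase gene, and FGFR3, a receptor tyrosine kinase gene, under the control of the immunoglobulin heavy chain locus. The series addresses how degrading NSD2 with NSD2LDD changes accessible chromatin in these lines. Peaks called in the 22 libraries covered 11.5 to 31.8 Mb (median 22.5 Mb), with a median peak width of 374 to 649 bp. Between 22.5% and 38.8% of peaks (median 29.4%) lay within 1 kb of a gene end and 19.4% to 30.0% (median 23.7%) outside genes. Peak number was 30946 ± 8439 in day 0 KMS11 and 28793 ± 2695 in TKO (mean ± SD, n = 2 libraries each). It spread most in KMS34 DMSO at day 4 (43341.5 ± 12978, n = 2). The covered bases of libraries of 1 group overlapped with a median Jaccard index of 0.583 (11 pairs). The index was 0.601 for libraries of different groups of a line (100 pairs) and 0.435 for libraries of different lines (120 pairs).

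**Figure D1:**
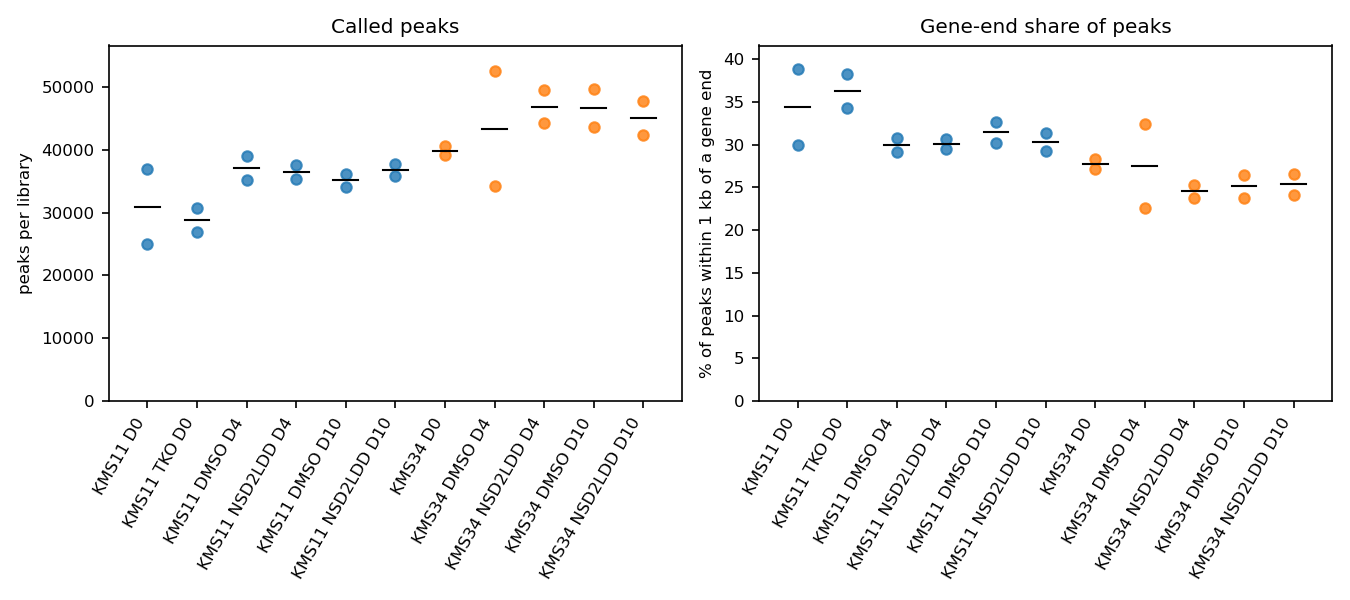
Peak number and share of peaks within 1 kb of a gene end in each of the 22 libraries, which ranged from 24979 to 52518 peaks and from 22.5% to 38.8%.

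NSD2 itself was covered by 374 to 1716 bp of peaks in the KMS11 libraries and by 690 to 4060 bp in the KMS34 libraries, counting its body and 5 kb either side. Its window overlaps NELFA, which encodes a subunit of the negative elongation factor. Coverage was 572 ± 280 bp in TKO and 476 ± 25.5 bp in day 0 KMS11 (mean ± SD, n = 2 each, log2 difference -0.0018 ± 0.51 SE, limma adjusted p = 0.999). Under NSD2LDD it was 1169.5 ± 401 bp against 1098 ± 239 bp in DMSO in KMS11 (0.03 ± 0.36, n = 4 each). In KMS34 it was 1517.5 ± 555 bp against 2439 ± 1381 bp (-0.47 ± 0.36), from -0.92 without KMS34_DMSO_D10 replicate 2 to -0.018 without replicate 1 of that group. Peak coverage measures neither NSD2 protein nor the integrity of the gene, so it checks neither the degradation nor the TKO label. FGFR3 had log2 differences of -0.01 ± 0.23, -0.23 ± 0.23 and 0.03 ± 0.32 under NSD2LDD in KMS11, in KMS34 and in TKO, in that order. MYC, a proliferation regulator, had 0.10 ± 0.11, -0.05 ± 0.11 and 0.08 ± 0.15. CCND2, a D-type cyclin gene, had 0.09 ± 0.12, -0.04 ± 0.12 and -0.59 ± 0.17 (adjusted p = 0.0575 in TKO). IRF4, a plasma cell transcription factor gene, had -0.16 ± 0.19, -0.35 ± 0.19 and 0.51 ± 0.26. MAF, a transcription factor gene activated in other myelomas, had -0.18 ± 0.12, -0.16 ± 0.12 and 0.24 ± 0.18. With KMS11_D0 replicate 2 and 1 left out in turn, TKO values were 0.22 and 0.81 for IRF4 and 0.11 and 0.36 for MAF, and FGFR3 was -0.69 and 0.74 without KMS11_TKO_D0 replicate 1 and 2. In KMS34, without KMS34_DMSO_D10 replicate 2 and 1, IRF4 was -0.54 and -0.16, MAF -0.31 and -0.018 and MYC -0.11 and 0.0034, and FGFR3 was -0.36 and -0.092 and CCND2 -0.10 and 0.021 without KMS34_NSD2LDD_D4 replicate 2 and 1. In KMS11, without KMS11_NSD2LDD_D10 replicate 2 and 1, IRF4 was -0.25 and -0.065 and FGFR3 -0.10 and 0.075. Without KMS11_NSD2LDD_D4 replicate 2 and 1, MYC was 0.0095 and 0.19 and CCND2 0.21 and -0.019, and MAF was -0.25 and -0.11 without KMS11_DMSO_D10 replicate 1 and 2. MYC in TKO was -0.0043 without KMS11_TKO_D0 replicate 2. None of these 6 genes passed the test in the 3 comparisons.

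In TKO, peaks were lost over PDE10A, a cyclic nucleotide phosphodiesterase gene (chr6:165327289-165988052). None was called there against 2887 ± 853 bp in day 0 KMS11 (mean ± SD, n = 2 libraries each, limma adjusted p = 8.34e-08). TKO also had no called peak over SLC4A4, a sodium bicarbonate cotransporter gene (2006 ± 518 bp in day 0 KMS11), and PTPRO, a receptor tyrosine phosphatase gene (2108 ± 1357 bp). The same held for ZMAT4, a zinc finger gene (2425.5 ± 1853 bp), and PPP1R9A, an actin-binding protein gene (1861 ± 376 bp). PDE1C, a calcium-dependent phosphodiesterase gene (1840 ± 902 bp), and RASEF, a Rab GTPase gene (1534 ± 101 bp), had none either. GRID1, a glutamate receptor family gene, fell from 3128 ± 812 to 251 ± 355 bp (log2 difference -3.27 ± 0.42 SE, adjusted p = 0.000189). KIAA1217, known for a role in the intervertebral disc, fell by 3.13 on the log2 scale (SE 0.22), and FABP7, a fatty acid binding protein gene, fell by 3.19 (SE 0.40).

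Coverage rose in TKO over LAIR1, an inhibitory immune receptor gene (chr19:54351384-54376088), from no called peak to 1655.5 ± 1033 bp (n = 2 each, limma adjusted p = 0.00056). Over ROBO2, an axon guidance receptor gene, it rose from 92.5 ± 131 to 1408.5 ± 276 bp (2.38 ± 0.45). CACNA1A, a calcium channel gene, rose by 2.06 ± 0.38, and DBF4B, a regulator of the kinase CDC7, by 1.98 ± 0.49. Peaks called in both TKO and in neither day 0 KMS11 library covered PTPRS, a receptor phosphatase gene (1114.5 ± 869 bp), and LRRC26, a potassium channel subunit gene (941.5 ± 438 bp). The same held for RAP1GAP2, a Rap1 GTPase activator gene (900.5 ± 339 bp), CYFIP1, a regulator of actin (936.5 ± 579 bp), and SYNDIG1, a synapse protein gene (752.5 ± 359 bp). The windows of PPP1R9A, PDE1C, FABP7, LRRC26, RAP1GAP2, CYFIP1 and DBF4B overlap those of neighbouring genes. RAP1GAP2 turned to -0.27 with 50 kb either side of its gene ends, and at the gene ends of PTPRS no peak was called in either group.

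**Figure D2:**
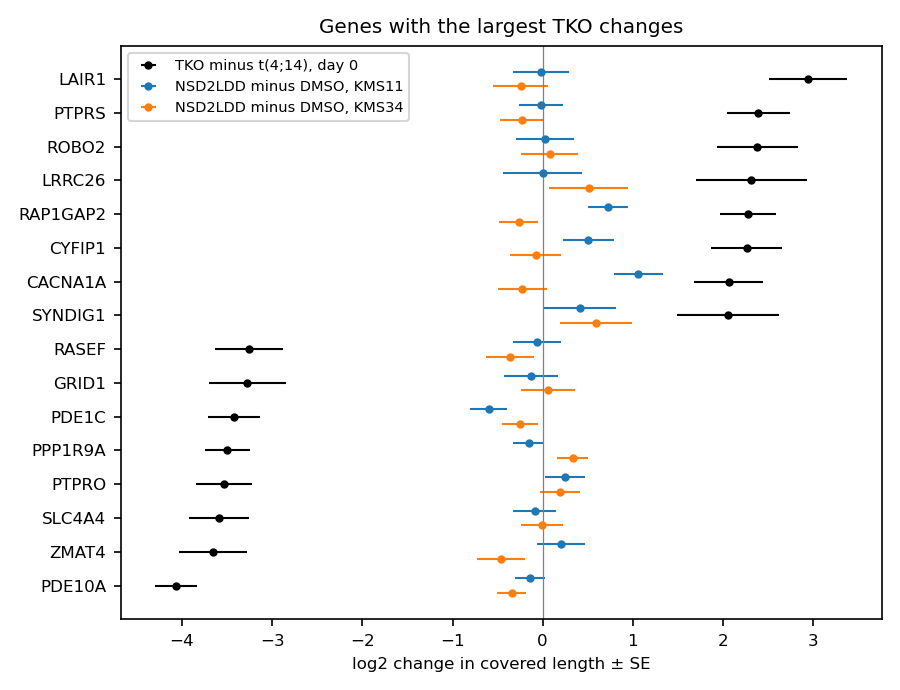
Log2 change in covered length (± SE) in TKO against day 0 KMS11 (n = 2 libraries each) and under NSD2LDD in each line (n = 4 each) for the genes with the 8 largest falls and 8 largest rises in TKO, among them GRID1 (-3.27 ± 0.42) and ROBO2 (2.38 ± 0.45). For genes with no called peak in 1 group, such as PDE10A and LAIR1, the plotted size depends on the bases added before the log2.

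Of 16738 genes tested in TKO, 559 fell and 226 rose (limma, adjusted p under 0.05, with 2691 at an unadjusted p under 0.05). Of 69187 regions, 2146 fell and 669 rose (8304 unadjusted). The excess of falls turned without KMS11_D0 replicate 1, with 473 lower and 794 higher genes and 1840 lower and 2149 higher regions. KMS11_D0 replicate 2, the 1 day 0 library left there, had the shortest list of the 22 libraries (24979 peaks). Against day 0 and DMSO KMS11 libraries together, chosen after seeing the data, the excess of falls held. There 835 genes were lower and 138 higher, and 3151 regions lower and 596 higher. The DMSO libraries come from days 4 and 10, and the lists were not of equal length. List length and day therefore cannot be told apart from an effect of TKO in this comparison. Of the 41 called genes named for TKO, 38 lost the call under some alternative, 22 with lists of equal length, 21 without scaling and 19 at gene ends alone. When 1 of the 4 libraries was left out, 19 lost it. Among these were LRRC26, SYNDIG1, DBF4B, CDH2, BCL11A, EBF1, CCND1, SPRY2, ICAM1, MX1, IFI44L, CDH1, KDM6B, FOXA1, MEIS2, POLR2A, TCF7 and COL1A1. Without KMS11_D0 replicate 1 and 2, 9 and 13 lost it, and without KMS11_TKO_D0 replicate 1 and 2, 15 and 12. Over the 22 fits that left out 1 library of either line, the call was lost in 19 for CDH2, 18 for SYNDIG1, 15 for MEIS2, 14 for LRRC26, 12 for SPRY2, 11 for IFI44L and 10 for CCND1.

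Members of the t(4;14) and NSD2 list fell in TKO, 3 lower and 0 higher of 13 (4 and 0 adjusted over the list alone). RRAS2, a RAS family gene, fell from 654.5 ± 131 bp to no called peak, and PAK1, a RAC-activated kinase gene, from 1925 ± 1216 to 671 ± 339 bp (log2 difference -1.36 ± 0.24 SE, n = 2 each). CDH2, which encodes N-cadherin, fell by 0.98 (SE 0.26), from -1.53 without KMS11_TKO_D0 replicate 2 to -0.42 without replicate 1, with the call lost in 19 of 22 fits that left out 1 library. Interferon genes were 3 lower and 0 higher of 33 (4 and 0 over the list alone). RSAD2, an antiviral enzyme gene whose window overlaps CMPK2, fell from 827 ± 728 bp to no called peak, as did IFI44L, an interferon-induced gene, from 295 ± 9.90 bp. MX1, an antiviral GTPase gene, fell by 1.27 (SE 0.30). Adhesion genes were 2 lower and 1 higher of 35 (3 and 1), namely CDH2, CDH1, the E-cadherin gene (-0.80 ± 0.19, and -0.52 without KMS11_D0 replicate 1), and ICAM1, a leukocyte adhesion receptor gene. ICAM1 rose from 337.5 ± 47.4 to 1552 ± 659 bp (1.51 ± 0.31) and was the 1 called member of the NF-kappaB list of 21 (0 and 2).

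Developmental regulators were 3 lower and 1 higher of 60 in TKO (3 and 2 over the list alone). GATA6 fell from 608.5 ± 555 bp and FOXA1 from 471.5 ± 155 bp to no called peak, MEIS2 fell by 0.67 (SE 0.18) and TBX2 rose by 1.77 ± 0.27. BCL11A (-0.96 ± 0.25, and -0.63 without KMS11_TKO_D0 replicate 2) and EBF1 (-0.97 ± 0.25), B cell transcription factor genes, made 2 lower and 0 higher of 19 B cell genes (2 and 1). CCND1, the cyclin D1 gene, rose from no called peak to 323.5 ± 51.6 bp, and SPRY2, an inhibitor of RAS signalling, fell by 0.89 (SE 0.24, and by 0.59 without KMS11_D0 replicate 2). They made 1 higher and 1 lower of 28 AP-1 and MAPK genes (1 and 1), and CCND1 was the 1 called cell cycle gene of 38 (0 and 0). KDM6B, an H3K27 demethylase gene, rose by 1.02 ± 0.24, 1 of 30 writers and erasers (1 over the list alone), and POLR2A, an RNA polymerase II subunit gene, by 0.75 ± 0.18, 1 of 31 housekeeping genes (1). TCF7, a T cell transcription factor gene, rose by 1.31 ± 0.32, 1 of 21 T and NK markers (2), and COL1A1, a collagen gene, by 0.68 ± 0.18, 1 of 20 stromal and endothelial markers (1). VCAN, a proteoglycan gene, fell by 0.79 (SE 0.14), 1 of 17 myeloid markers (1). Windows also overlap neighbouring genes at RRAS2, MX1, IFI44L, CDH1, ICAM1, FOXA1, TBX2, CCND1, KDM6B, POLR2A, TCF7 and COL1A1. At the gene ends of CCND1 no peak was called in day 0 KMS11 or TKO.

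The plasma cell list (24 genes), antigen presentation (22), apoptosis (28) and the erythroid and megakaryocyte markers (15) held 0 genes called by limma in TKO over all genes. Over the list alone they held 0 except 2 higher apoptosis genes. Without scaling, the median over all genes moved from -0.03 to 0.11 in TKO and that over regions from -0.14 to 0. Then 164 genes were lower and 45 higher, and none of the 21 list members called in TKO turned direction.

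The largest falls among regions in TKO were each called in 2 of 2 day 0 KMS11 and 0 of 2 TKO libraries. They lay at KHDRBS2, an RNA-binding protein gene (chr6:61886740-61888434, 1436.5 ± 194 bp in day 0 KMS11), and SERTAD4, a SERTA domain gene (chr1:210232261-210234513, adjusted p = 4.41e-09). The others lay at B4GALT6, a lactosylceramide synthase gene (chr18:31658264-31659738, 1201 ± 1.41 bp), PDE10A (chr6:165661562-165663819, 1175.5 ± 99.7 bp) and KBTBD11, a Kelch repeat gene (1169.5 ± 37.5 bp). Regions called in both TKO and neither day 0 KMS11 library rose at GSE1, a subunit gene of a histone deacetylase complex (chr16:85447124-85449247, 1039.5 ± 186 bp, adjusted p = 0.00134). They also rose at CELF5, an RNA-binding protein gene (858 ± 49.5 bp), and MOXD1, a monooxygenase-like gene (818.5 ± 309 bp). A further pair lay 162964 bp from CAND1, a ubiquitin ligase exchange factor gene (1466.5 ± 301 bp), and 24686 bp from DENND1B, a vesicle traffic gene (1008.5 ± 401 bp). These lost the call when 1 library of either group was left out.

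Of regions called in both day 0 KMS11 libraries, 1.81% of those within 1 kb of a gene end (163 of 8994) were called in neither TKO library. The share was 18.9% in protein-coding gene bodies (1078 of 5714), 21.7% in other gene bodies (447 of 2057) and 29.1% between genes (1072 of 3684). More than 50 kb from a protein-coding gene it was 37.1% (1043 of 2812). Regions gained in TKO made up 1.46%, 12.1%, 9.45%, 12.3% and 11.2% of the regions called in both TKO libraries, in the same order of classes. Of regions called by limma, 12.6% of the falls and 23.2% of the rises in TKO lay at gene ends, against 18.4% of tested regions. Genes that fell in TKO had a median length of 156 kb, those that rose 24.3 kb and all tested genes 30.4 kb. These shares and lengths carry no test, and peak strength was not matched between classes. The lost and gained shares rest on 2760 and 1307 regions. These numbers became 1061 and 1279 when a large part of the region had to be covered, so the balance of losses and gains turned.

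**Figure D3:**
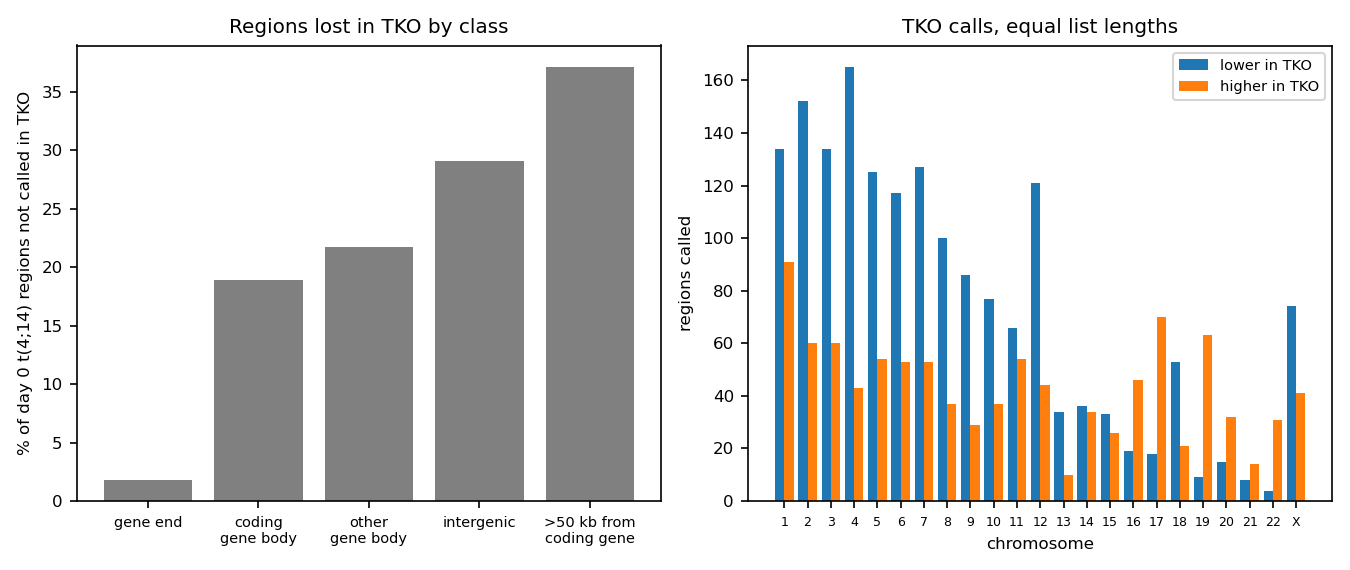
Left, share of regions called in both day 0 KMS11 libraries and in neither TKO library by position, from 1.81% at gene ends to 37.1% more than 50 kb from a protein-coding gene. Right, regions called lower and higher in TKO by chromosome with lists of equal length, with lower calls outnumbering higher ones on 17 of 23 chromosomes.

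Under NSD2LDD in KMS11, peaks called in 4 of 4 DMSO and 0 of 4 NSD2LDD libraries were lost inside SORCS3, a sorting receptor gene (chr10:104809274-104809972, 365 ± 70.2 bp in DMSO, mean ± SD, limma adjusted p = 0.00121). The same held inside CREB5, a transcription factor gene (360.75 ± 119 bp), and 46716 bp from MYO16, a myosin gene (413.25 ± 129 bp). It also held 77356 bp from DOK5, an adaptor protein gene (380.75 ± 57.5 bp), and 170201 bp from PROK2, a secreted peptide gene (352.75 ± 115 bp). Peaks called in 4 of 4 NSD2LDD and 0 of 4 DMSO libraries were gained inside DROSHA, a microRNA processing gene (chr5:31496261-31496859, 380.75 ± 105 bp). A gain inside PWWP2A, which encodes a chromatin reader, covered 354.5 ± 91.5 bp (chr5:160068820-160069580, adjusted p = 0.00781). The other gains lay 170869 bp from C1QTNF3, a secreted protein gene (385.5 ± 200 bp), 554105 bp from RPIA, a pentose phosphate enzyme gene (488.25 ± 195 bp), and 835326 bp from CSMD3, a membrane protein gene (442.25 ± 105 bp). In all 22 regions fell and 26 rose of 69187 (3321 at an unadjusted p under 0.05), 42 of the 48 in the same direction at both days, which calling on the mean of both days favours. None lay at gene ends (0%), against 18.4% of tested regions. No gene of 16738 passed in limma (586 unadjusted), while limma without trend and robust called 3 and lists of equal length gave 1 lower and 3 higher genes. All 10 named regions lost the call in a fit of KMS11 libraries alone, which called 0 regions (2051 unadjusted), and those at MYO16, DOK5, CREB5, RPIA, DROSHA and C1QTNF3 (6 of 10) when 1 library was left out. The count ran from 31 without KMS34_NSD2LDD_D10 replicate 1 to 85 without KMS11_NSD2LDD_D10 replicate 1, and other splits of the same 8 libraries gave up to 315 regions against 39 for the real one in the same fit.

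In KMS34, peaks were lost under NSD2LDD inside TSPAN18, a tetraspanin gene (chr11:44726963-44728226), with 500.75 ± 163 bp in DMSO and none called under NSD2LDD (n = 4 libraries each, limma adjusted p = 0.00144). None was called under NSD2LDD inside CACNA1D, a calcium channel gene (470.5 ± 213 bp in DMSO), and 137943 bp from SCN7A, a sodium channel gene (482.25 ± 228 bp). Coverage fell inside NKAIN3, a sodium pump interacting protein gene, from 829 ± 287 to 68.75 ± 138 bp (log2 difference -2.65 ± 0.51 SE). At 52998 bp from NECTIN1, a cell adhesion gene, it fell from 772.5 ± 166 to 93.25 ± 186 bp (-2.52 ± 0.39). Peaks called in 4 of 4 NSD2LDD and 0 of 4 DMSO libraries were gained inside ROBO2 (chr3:77319853-77320733, 553.5 ± 344 bp, adjusted p = 0.00136) and SRBD1, an RNA-binding domain gene (553.25 ± 167 bp). Further gains lay 6719 bp from SMYD3, a lysine methyltransferase gene (484.5 ± 139 bp), 39982 bp from TMEM154, a membrane protein gene (448.25 ± 207 bp), and 887801 bp from PLOD2, a collagen-modifying enzyme gene (578.25 ± 143 bp). In all 238 regions fell and 444 rose (6833 at an unadjusted p under 0.05), 591 of the 682 in the same direction at both days, which calling on the mean of both days favours. The excess of rises turned without KMS34_DMSO_D4 replicate 1 (323 falls and 166 rises), and with lists of equal length there were 345 and 343. Of the falls 14.3% lay at gene ends, and of the rises 2.03%. No gene passed in limma (1044 unadjusted), while limma without trend and robust called 6 and lists of equal length gave 41 lower and 6 higher genes. The count of regions ran from 114 without KMS11_NSD2LDD_D4 replicate 2 to 886 without KMS34_DMSO_D10 replicate 2, and a fit of KMS34 libraries alone called 6 regions and none of the 10 named. When 1 library was left out, 5 of the 10 lost the call, at CACNA1D (in 22 of 22 fits), SRBD1 (18), NKAIN3 (15), PLOD2 (11) and TMEM154 (11). Each fit that left out 1 KMS11 library called fewer than the 682 regions, though no KMS11 library is in this comparison. The count of 682 therefore depends on libraries outside the comparison. Other splits of the same 8 libraries gave up to 249 regions against 98 for the real one in the same fit.

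The effect of NSD2LDD differed between the lines at 4 of 69187 regions, 2 lower and 2 higher in KMS34 (4141 at an unadjusted p under 0.05). With replicate number as a block limma called 0 (4070 unadjusted). Inside SORCS3 no peak was called under NSD2LDD in KMS11 against 365 ± 70.2 bp in DMSO, while KMS34 had 578.5 ± 8.70 and 580 ± 81.2 bp (mean ± SD, n = 4 each, limma adjusted p of the difference 0.0402). Inside DCLK2, a microtubule-associated kinase gene, none was called under NSD2LDD in KMS34 against 310.25 ± 98.7 bp in DMSO, and KMS11 had 1269.25 ± 59.8 and 1289.5 ± 92.9 bp (0.0241). Inside NTRK2, a neurotrophin receptor gene, peaks were called in 4 of 4 DMSO and 0 of 4 NSD2LDD libraries of KMS34, and in 0 of 4 and 2 of 4 of KMS11 (0.0275). At 32532 bp from NEUROD6, a neuronal transcription factor gene, the log2 effect was -1.86 in KMS11 and 0.10 in KMS34 (0.0275). The count ran from 0 without KMS11_DMSO_D4 replicate 1 to 18 without KMS34_DMSO_D4 replicate 2. No gene differed in limma (556 unadjusted), while with lists of equal length 7 were lower and 2 higher. Called regions of the lines had 0 falls and 1 rise in common, against 0.0757 and 0.167 if independent, and the effects of all tested regions correlated with r = 0.0624. Of the KMS11 regions called under NSD2LDD, 10 falls and 4 rises were also called in TKO in the same direction (0.682 and 0.251 if independent) and 1 in the opposite direction. In KMS34, 16 falls and 2 rises were shared with TKO in the same direction (7.38 and 4.29 if independent) and 3 regions in opposite directions (16.1 if independent). Over all regions the effects correlated with TKO by r = 0.0900 in KMS11 and 0.0257 in KMS34.

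None of the 17 gene lists held a gene called under NSD2LDD in KMS11 or KMS34 over all genes. Over the list alone the developmental regulators in KMS34 held 1 lower and 1 higher gene and the others none. The mean of the antigen presentation list was 0.08 higher under NSD2LDD on the log2 scale over both lines (exact permutation p = 0.0386, higher in 4 of 4 pairs of line and day). With lists of equal length it was -0.0024, and 11 of 16 fits without 1 library gave an exact permutation p of 0.05 or more. That of the plasma cell list was 0.05 higher (exact permutation p = 0.0556, in KMS34 alone 0.10, p = 0.0286, there -0.043 with lists of equal length). With all 17 lists adjusted together the lowest exact permutation p was 0.472. Peak number was 720.25 higher under NSD2LDD (exact permutation p = 0.816). The share of peaks at gene ends differed by -0.923 percentage points and that outside genes by 0.130 (exact permutation p = 0.586 and 0.894).

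Regions lost in TKO (2760, called in both day 0 KMS11 and neither TKO library) were mostly called in the other KMS11 libraries. At day 4 their share was 90.3 ± 1.10% in DMSO and 87.8 ± 1.69% under NSD2LDD, and at day 10 it was 80.7 ± 6.07% and 75.7 ± 0.615% (mean ± SD, n = 2 each). The NSD2LDD minus DMSO difference in KMS11 was -3.75 percentage points (-2.52 at day 4 and -4.98 at day 10). Labels exchanged over all 8 libraries, ignoring day, gave an exact permutation p of 0.40. Exchanged within day, chosen after seeing the data, they gave an exact permutation p of 0.0556, the lowest that 36 relabellings can give. With both days weighted alike the difference ran from -5.90 without KMS11_DMSO_D10 replicate 1 to -1.60 without replicate 2 of that group. Over both lines it was -2.82, and with lists shortened to the same length -4.57 (exact permutation p = 0.340 and 0.0170, both chosen after seeing the data). Against kept regions of matched strength at day 0 the difference over both lines was -3.37 (exact permutation p = 0.130, also chosen after seeing the data). Regions called in TKO alone (1307) were 6.06 percentage points more often called under NSD2LDD in KMS11 (exact permutation p = 0.371 ignoring day and 0.333 within day, the latter chosen after seeing the data). With lists of equal length 2410 regions were lost and 1857 gained in TKO. When a large part of the region had to be covered, the excess of losses turned, with 1061 lost and 1279 gained.

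**Figure D4:**
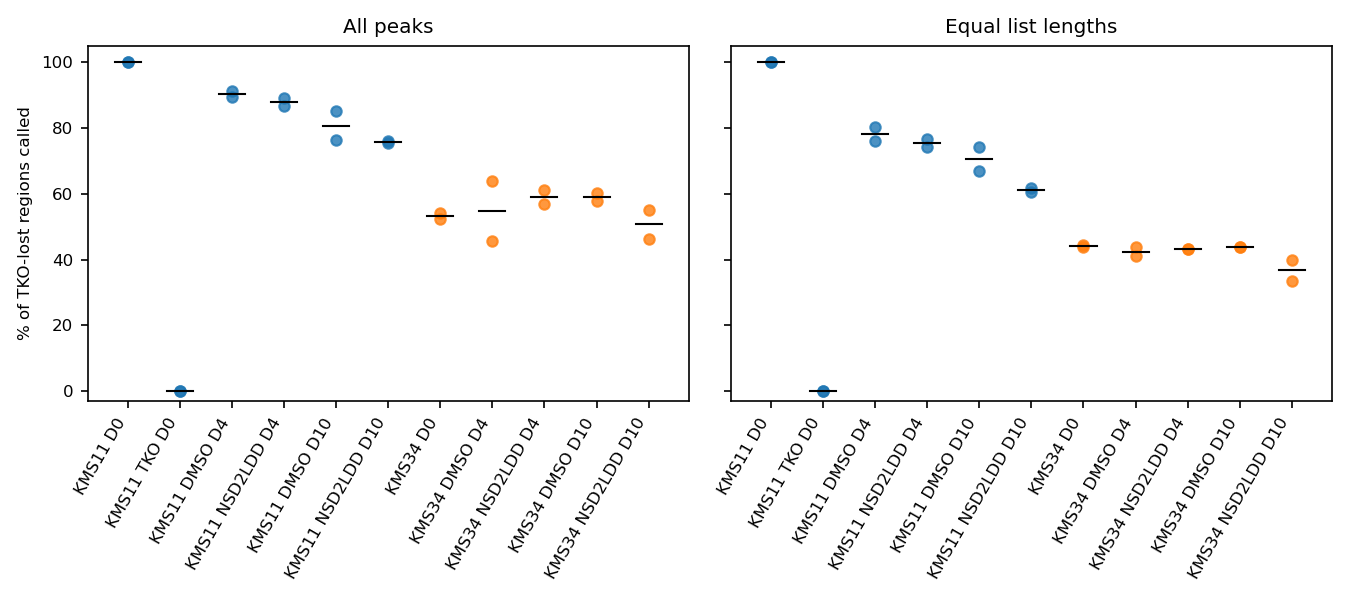
Share of the regions lost in TKO that were called in each of the 22 libraries, with all peaks (left, 2760 regions) and with lists of equal length (right). With all peaks the KMS11 means were 90.3% (DMSO) and 87.8% (NSD2LDD) at day 4 and 80.7% and 75.7% at day 10.

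Between the lines at baseline (day 0 and DMSO libraries, n = 6 each), KCNK1, a potassium channel gene, was covered by 5960 ± 1258 bp of peaks in KMS11 and 114.5 ± 126 bp in KMS34 (mean ± SD). Its log2 difference was -4.58 ± 0.17 (SE, limma adjusted p = 2.89e-11). KMS34 had no called peak over NAV3, a neuron navigator gene (3324 ± 1179 bp in KMS11), ADTRP, a regulator of coagulation (2364 ± 861 bp), and ZIC2, a developmental transcription factor gene (1858 ± 544 bp). The same held for SYCE2, a meiotic gene, ANKRD23, a muscle ankyrin repeat gene, TECRL, a reductase-like gene, CSRP2, a LIM domain gene, and TBX18, a T-box gene. EVL, an actin regulator, was lower in KMS34 (68.0 ± 105 against 2208 ± 907 bp, -3.39 ± 0.21). KMS11 had no called peak over ADGRD1, an adhesion GPCR gene (3243 ± 1347 bp in KMS34), and AJAP1, an adherens junction gene (2898 ± 1357 bp). It had none at the gamma protocadherin locus either, where PCDHGA2, PCDHGA3, PCDHGA4, PCDHGA5, PCDHGA6, PCDHGB1, PCDHGB2 and PCDHGB3 share 1 window (2970 ± 405 bp in KMS34). FGFR3 (0.67 ± 0.19), MYC (0.36 ± 0.09), CCND2 (0.50 ± 0.10) and MAF (0.74 ± 0.10) were higher in KMS34. NSD2 was 0.80 ± 0.29 higher (adjusted p = 0.0433), a call lost in 12 of 22 fits that left out 1 library and turned to -0.72 ± 0.68 with lists of equal length. IRF4 differed by -0.0047. MAF turned to -0.076 at gene ends alone and CCND2 to -0.069 with 50 kb either side of gene ends. The windows of ZIC2, SYCE2, ANKRD23, CSRP2, EVL, FGFR3, MAF and NSD2 overlap those of neighbouring genes.

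Plasma cell genes went both ways between the lines, 6 lower and 7 higher in KMS34 of 24 (6 and 7 adjusted over the list alone). SDC1, which encodes the plasma cell antigen CD138, was covered by 6124 ± 1752 bp in KMS34 and 1966.5 ± 713 bp in KMS11 (1.37 ± 0.15, n = 6 each), and GPRC5D, a receptor gene, by 738.8 ± 314 bp and none. IKZF3, the gene of the transcription factor Aiolos (-1.42 ± 0.11), and SEL1L, a gene of protein quality control (-1.10 ± 0.10), were lower. B cell genes were 2 lower (BLK, a kinase gene, -0.75, and CD74, -0.61) and 6 higher of 19 (2 and 6). Among the higher were CD79B, a B cell receptor subunit gene called in KMS34 alone, EBF1 (1.57 ± 0.15) and CD40 (1.71 ± 0.28). Antigen presentation was 1 lower (CD74) and 5 higher of 22 (1 and 5). Among the higher were HLA-DPB1 (2.01 ± 0.30) and HLA-DPA1 (1.80 ± 0.28), whose windows overlap, HLA-DMA (0.61) and HLA-B (0.51). The t(4;14) and NSD2 list was 2 lower (DSG2, a desmosome gene, -0.33, and TGFA, a growth factor gene, -0.25) and 7 higher of 13 (3 and 8). Among the higher were CLEC11A, a growth factor gene (window shared with SHANK1) with no called peak in KMS11, PTP4A3, a phosphatase gene (1.42 ± 0.19), and MET, a receptor kinase gene (1.12 ± 0.11). At gene ends alone BLK (0.28) and HLA-DMA (-0.053) turned direction.

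Interferon genes were 4 lower (among them STAT2 -0.82, IRF7 -0.80 and USP18 -0.68) and 8 higher in KMS34 of 33 (4 and 8 over the list alone). OAS3 (1.38 ± 0.22), OAS2 (0.79 ± 0.13) and GBP2, with no called peak in KMS11, were higher. NF-kappaB genes were 6 lower and 5 higher of 21 (6 and 5). TNFAIP2, a TNF-induced gene, was called in KMS11 alone and TRAF2, a signalling adaptor gene, was lower (-0.71). The higher ones were TNF, called in KMS34 alone, CD40, LTB (1.14), ICAM1 (0.55) and NFKBIZ (0.38). Writers and erasers were 6 lower and 3 higher of 30 (5 and 2). ASH1L (-1.49 ± 0.11) and EZH1 (-1.02 ± 0.11), which encode methyltransferases of H3K36 and H3K27, DNMT1 (-0.92) and EED (-0.71) were lower, and KDM6B (0.92), NSD2 and KDM2B (0.45) higher. Cell cycle genes were 2 lower (E2F7, called in KMS11 alone, and CDC6, -0.60) and 8 higher of 38 (2 and 8), with CCND1 at 1.54 ± 0.19 and CDKN1A, the p21 gene, at 0.79 ± 0.17. Apoptosis genes were 6 lower and 4 higher of 28 (6 and 4), among the higher FADD (0.72), BCL2L1 (0.35) and APAF1 (0.29). AP-1 and MAPK genes were 3 lower (EPHA2 -1.17, SPRED2 -0.58 and DUSP4 -0.38) and 3 higher of 28 (2 and 2), CCND1, PHLDA1 (0.30) and FOSL1 (0.23). Adhesion genes were 7 lower, with CADM1 at -1.38 ± 0.15 and NRCAM at -0.63, and 9 higher of 35 (7 and 10), with ITGB3 at 1.88 ± 0.21 and ITGB2 not called in KMS11. Developmental regulators were 16 lower, with ZIC2, IRX3 and ISL1 called in KMS11 alone, and 14 higher of 60 (16 and 14), with TBX2 at 1.79 ± 0.16. Housekeeping genes were 7 lower, among them PSMB4 (-0.88) and RPL13A (-0.44), and 4 higher of 31 (7 and 4), among the higher RPS18 (0.34), POLR2A (0.32) and VPS29 (0.26). Genes beyond the 4 of each list that the rule names were chosen after their values were seen. Windows overlap neighbouring genes at TNF, FOSL1, STAT2, OAS2, OAS3, GBP2, ASH1L, EZH1, CCND1, TBX2, PSMB4 and RPL13A. At gene ends alone TRAF2 (0.54), ITGB2 (-0.19), BCL2L1 (-0.031) and DNMT1 (0.065) turned direction, and with lists of equal length FADD (-1.15). Of the 171 list members called between the lines none turned without scaling or with quantile normalization, but sizes moved by over 1.5 times for 31 (smaller) and 17 (larger) without scaling and for 8 and 3 with quantile normalization. Without scaling TGFA was -0.033 and DSG2 -0.11.

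In all 2461 genes were lower and 3499 higher in KMS34 than in KMS11 (7425 of 16738 at an unadjusted p under 0.05), and 9835 regions were lower and 13862 higher. With lists of equal length 7855 regions were lower and 6870 higher, and with log2 peak number as a covariate 8369 and 8017. Without scaling 7514 and 16684 regions and 944 and 4265 genes were lower and higher, and with quantile normalization 3041 and 2961 genes. The median over all genes was 0.03 with scaling and 0.25 without, and that over regions 0.14 and 0.32. Of the 87 called genes named between the lines, 3 lost the call when 1 library was left out (NSD2, FOSL1 and S100A9). Under any alternative 37 lost it, 22 of them at gene ends alone and 17 with lists of equal length.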

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

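Libraries of days 4 and 10 of a line and treatment were pooled as 4 samples, and 112 such sets of values were searched for 1 library far from the other 3. Chance gives such a library in about 1 of 20 sets, and 8 were found, so their number is near what chance gives. The share of peaks outside genes was 22.1% in KMS11_DMSO_D10_1 (23.3% to 23.6% in the other 3) and 27.6% in KMS34_NSD2LDD_D10_2 (29.1% to 29.2%). List means on the log2 scale stood apart in KMS34_DMSO_D10_2 for the t(4;14) and NSD2 list (0.48 against 0.70 to 0.72), in KMS34_NSD2LDD_D4_1 for NF-kappaB (-0.048 against 0.11 to 0.13), in KMS11_NSD2LDD_D10_1 for apoptosis (0.77 against 0.93 to 0.96) and in KMS34_DMSO_D10_1 for stromal and endothelial markers (-0.37 against -0.60 to -0.58). The log2 coverage of NSD2 was 9.62 in KMS34_NSD2LDD_D10_2 (10.77 to 10.99 in the other 3), and that of FGFR3 was 10.40 in KMS11_DMSO_D4_2 (10.08 to 10.13).

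The NSD2LDD effect differed between KMS34 and KMS11, by the test of the difference itself, at 4 regions on the log2 scale (0 with replicate number as a block, 4070 unadjusted). The difference was -1.96 inside DCLK2, a microtubule-associated kinase gene (chr4:150078312-150079901, adjusted p = 0.0241), and -2.79 inside NTRK2, a neurotrophin receptor gene (chr9:84697491-84697914, 0.0275). It was 1.96 near NEUROD6, a neuronal transcription factor gene (chr7:31373259-31374406, 32532 bp away, 0.0275), and 2.24 inside SORCS3, a sorting receptor gene (chr10:104809274-104809972, 0.0402). At DCLK2, NTRK2 and SORCS3 a group had no called peak, so the size of the difference there depends on the bases added before the log2. Chance cannot be excluded for their number, since 36 of 100 splits of the libraries within each line gave as many regions as the real one in the same fit (70, highest other 254).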

How the results depend on the processing

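The comparison of TKO with day 0 and DMSO KMS11 libraries together, and the tests of regions lost in TKO within day, over both lines or against matched kept regions, were chosen after seeing the data, and all other alternatives were planned. Values were recomputed for counts, peak number, shares of peaks and of regions lost in TKO, and the correlation between lines. Of these, 296 were the same, 112 counts or values moved, 7 reversed and 1 became stronger. Tested values were the same when they kept their direction and side of the threshold. Counts of calls were compared by the total of lower and higher calls, so a turned balance can count as the same. This was so for regions changed in TKO without KMS11_D0 replicate 1, where the excess of falls turned. Of the values recomputed for single named genes, regions, list means and the lower shares of calls, 6151 were the same, 557 became weaker, 15 stronger, 7 moved and 117 reversed. The cause of these changes was not tested. Depth is unknown, so it cannot be said which regions were too shallow to be called. Motif shares were not run, because no sequence was held, an exact test of called or not could pass the threshold between the lines alone, and a fit within 1 line cannot give a difference between lines. Leaving out 1 library leaves an arm of 1 library in groups of 2, which is assumed to vary like the other groups.

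Regions changed by NSD2LDD in KMS11 numbered 107 with peaks of -log10 q of 5 or more, 306 with equal list lengths, 237 without scaling, 287 with quantile normalization, 0 in a fit within the line (2051 at an unadjusted p under 0.05), 359 in limma without trend and robust, 380 and 8 with 30 and 300 bp added, 24 when called in at least 1 library, 590 in summit windows and 551 as called or not. Regions changed by NSD2LDD in KMS34 numbered 1385 without scaling, 6 within the line, 1536 without trend and robust, 1538 and 80 with 30 and 300 bp added, 178 and 93 when called in at least 4 libraries and 1 library, 1613 in summit windows and 1539 as called or not. Regions whose NSD2LDD effect differs between lines numbered 31 with peaks of -log10 q of 5 or more, 155 with equal list lengths, 71 without scaling, 189 with quantile normalization, 120 without trend and robust, 95 and 0 with 30 and 300 bp added (3679 unadjusted with 300 bp), 1 when called in at least 1 library, 1356 in summit windows and 1267 as called or not. With replicate number as a block these 3 counts were 23, 101 and 0 (4070 unadjusted), and the block changed no other call count by over 1.5 times. Across days the numbers do not pair the libraries consistently. Correlations of same-numbered libraries ran from -0.21 to 0.27 over genes and from -0.17 to 0.21 over regions in KMS11 (15 pairs of groups, 2 above 0.1 in each). In KMS34 they ran from -0.20 to 0.18 (2 of 10) and -0.13 to 0.09 (0 of 10). Both KMS11 pairs above 0.1 were of 1 day, DMSO with NSD2LDD at day 10 (0.27 and 0.21) and day 0 with TKO (0.19 and 0.12). DMSO with NSD2LDD gave 0.076 and 0.067 at day 4 in KMS11. In KMS34 it gave 0.15 and 0.089 at day 4 and -0.097 and -0.029 at day 10. A pairing within day therefore stays open, since the block in limma held 1 term for each line and none for each day.

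Regions differing between lines at baseline numbered 14725 with equal list lengths and 11395 in the exact test of called or not, and the lower share of region calls turned to 53.3% with equal list lengths and 51.1% with log2 peak number as a covariate. Genes differing between lines at baseline numbered 9009 with 50 kb either side and 2806 at gene ends alone, and the lower share of gene calls turned to 50.7% with quantile normalization. Genes changed in KMS11 TKO numbered 209 without scaling, 465 with 1000 bp added, 1197 with 50 kb either side and 365 at gene ends alone. Against day 0 and DMSO KMS11 libraries together 835 genes were lower and 138 higher, and 3151 and 596 regions. Genes changed by NSD2LDD in KMS11 numbered 2 with peaks of -log10 q of 5 or more, 4 with equal list lengths, 1 without scaling, 1 with quantile normalization, 3 without trend and robust, 2 with 50 bp added, 2 with 50 kb either side and 1 when covered in at least 11 libraries. In KMS34 they numbered 47 with equal list lengths, 3 without scaling, 4 with the covariate, 6 without trend and robust, 6 and 2 with 50 and 1000 bp added and 1 at gene ends alone. The correlation of NSD2LDD effects between lines was 0.0604 with equal list lengths and 0.0736 for regions called in at least 4 libraries, and the change of regions lost in TKO over both lines with equal list lengths was -4.57.

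At gene ends alone, log2 differences turned for NSD2 (-0.16) and FGFR3 (0.22) under NSD2LDD in KMS11, MYC in KMS34 (0.17), PTPRS (-0.14), CCND1 (-0.14, both without a called peak there in either group, so from scaling alone) and MAF (-0.0019) in TKO, and, between lines, for IRF4 (0.25), MAF (-0.076), BLK (0.28), TRAF2 (0.54), HLA-DMA (-0.053), ITGB2 (-0.19), BCL2L1 (-0.031), DNMT1 (0.065), CD247 (1.76) and ITGAM (0.027). With 50 kb either side of gene ends they turned for CCND2 in KMS11 (-0.026), MYC in KMS34 (0.057), RAP1GAP2 (-0.27), NSD2 (0.12) and MYC (-0.10) in TKO and CCND2 (-0.069), IRF4 (0.033) and S100A9 (-1.28) between lines. With equal list lengths they turned for NSD2 (-0.72) and MYC (-0.074) in KMS11, NSD2 (0.62), MYC (-0.016) and MAF (-0.11) in TKO and NSD2 (-0.72) and FADD (-1.15) between lines. With peaks of -log10 q of 5 or more they turned for NSD2 in KMS11 (-0.019), MYC (0.0073) and CCND2 (0.00061) in KMS34, NSD2 in TKO (0.85) and IRF4 between lines (0.049). Without scaling FGFR3 in KMS11 (0.0060), NSD2 in TKO (0.14) and IRF4 between lines (0.21) turned, NSD2 in TKO also with quantile normalization (0.030) and the covariate (0.023), FGFR3 in TKO with 50 bp added (-0.036), and FGFR3 (-0.15) and MAF (-0.11) in TKO against day 0 and DMSO libraries together. List means under NSD2LDD turned with 50 kb either side for t(4;14) and NSD2 (0.050), B cell (-0.044), NF-kappaB (-0.017), housekeeping (-0.0047) and stromal and endothelial lists (0.027), with equal list lengths for B cell (-0.042), antigen presentation (-0.0024), housekeeping (-0.0036), myeloid (0.11) and stromal and endothelial lists (0.0019), and with peaks of -log10 q of 5 or more for housekeeping (-0.0091).

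Leaving out 1 library in turn, regions changed by NSD2LDD ran from 31 without KMS34_NSD2LDD_D10 replicate 1 to 85 without KMS11_NSD2LDD_D10 replicate 1 in KMS11 and from 114 to 886 in KMS34, regions whose effect differs between lines from 0 to 18, genes changed from 0 to 3 in KMS11, from 0 to 6 in KMS34 and from 521 to 1267 in TKO. The lower share of TKO calls ran from 46.1% to 87.4% for regions and from 37.3% to 82.0% for genes, both lowest without KMS11_D0 replicate 1. Peak number under NSD2LDD changed by -1573.9 to 3014.4, the share at gene ends by -2.16 to 0.315 and that outside genes by -0.385 to 0.645 percentage points, the extremes being without KMS34_DMSO_D4 replicate 1 or 2. The change of regions lost in TKO in KMS11 ran from -6.78 to -1.59 percentage points with days unbalanced and from -5.90 to -1.60 with both days weighted alike. Ranges across 0 were found for NSD2 (-0.17 to 0.24), FGFR3 (-0.10 to 0.075) and CCND2 (-0.019 to 0.21) in KMS11, MYC (-0.11 to 0.0034) and CCND2 (-0.10 to 0.021) in KMS34, NSD2 (-0.28 to 0.27), FGFR3 (-0.69 to 0.74) and MYC (-0.0043 to 0.17) in TKO and IRF4 between lines (-0.13 to 0.12). Lists with ranges across 0 were B cell (-0.018 to 0.027), NF-kappaB (-0.014 to 0.031), adhesion (-0.0068 to 0.046), cell cycle (-0.014 to 0.040), apoptosis (-0.010 to 0.032), housekeeping (-0.016 to 0.016), T and NK (-0.069 to 0.00080), myeloid (-0.062 to 0.0045), erythroid and megakaryocyte (-0.029 to 0.055) and stromal and endothelial (-0.047 to 0.010).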

Other observations

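The tests of chromosome loss, loss of NSD2 and GC content in TKO, both tests of the fall at day 10, the comparison with KMS34 for shared regions and the counts over other splits were chosen only after the results were seen.

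The largest falls among regions between the lines were inside TMTC1, a protein glycosylation gene (2118.5 ± 367 bp in KMS11, mean ± SD, and none called in KMS34, n = 6 each), PIP4K2A, a lipid kinase gene (1713 ± 361 bp), CNDP1, a dipeptidase gene (1683 ± 151 bp), and ZIC2, and 40775 bp from MEF2C, a transcription factor gene (2003 ± 196 bp). The largest rises lay at the histone genes H2BC3 (1935.5 ± 304 bp in KMS34 and none called in KMS11) and H2AC25 (1892 ± 196 bp), at GDF7, a growth factor gene (1757.5 ± 200 bp), inside ERBB4, a receptor kinase gene (1722 ± 199 bp), and 58932 bp from TMEM121, beside the immunoglobulin heavy chain locus (2028 ± 183 bp). Markers of other cell types went both ways between the lines. Among T and NK markers CD8B (-1.58), IL7R (-1.57) and CD247 (-0.57) were lower in KMS34, and NKG7 and TBX21, with no called peak in KMS11, TRAT1 (0.97) and EOMES (0.34) were higher, 3 and 4 of 21 (3 and 4 adjusted over the list alone). Myeloid markers were 4 lower (ITGAM -1.31, ELANE -1.21, CSF3R -0.82 and FCGR1A -0.38) and 3 higher of 17 (S100A9 0.82, LYZ 0.58 and TYROBP 0.55, 4 and 3). Erythroid and megakaryocyte markers were 3 lower (HBB, with no called peak in KMS34, HBA1 -1.61 and HBD -0.55) and 5 higher of 15 (among them ITGB3 1.88, GYPB 1.36, GP1BA 0.93 and ANK1 0.82, 3 and 5), and stromal and endothelial markers 3 lower (KDR -2.25, COL3A1 -1.98 and PDGFRA -0.41) and 4 higher of 20 (CXCL12 2.46, COL1A2 1.16, VWF 1.00 and CDH5 0.62, 3 and 4). At gene ends alone CD247 (1.76) and ITGAM (0.027) turned direction, and S100A9 (-1.28) with 50 kb either side of gene ends. With quantile normalization LYZ was 0.086 and S100A9 0.26. Members beyond the 4 of each list that the rule names were chosen after their values were seen.

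By day, NSD2LDD gave 70 lower and 94 higher regions in KMS11 at day 4 and 109 and 135 at day 10 (2 libraries against 2), with 4 falls and 5 rises in common (0.110 and 0.183 if independent). In KMS34 it gave 116 and 352 at day 4 and 554 and 497 at day 10, with 14 falls and 39 rises in common (0.929 and 2.53 if independent). At day 10 in KMS11 1 gene was lower and 1 higher, at day 10 in KMS34 2 were lower, and at day 4 limma called 0 genes in either line (455 in KMS11 and 799 in KMS34 at an unadjusted p under 0.05).

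More regions were lower than higher in TKO (2146 and 669). With lists of equal length they were 1707 and 1003, a lower share of 63.0%. Without KMS11_D0 replicate 1 the share was 50.6% (95% interval 48.8% to 52.5%, a bound added after the value was seen). It was 55.4% without KMS11_D0 replicate 2, and 81.2% and 76.8% without KMS11_TKO_D0 replicate 1 and 2. The excess of falls thus depended on KMS11_D0 replicate 1. KMS11_D0 replicate 2, the 1 day 0 library left without it, had the shortest list of all 22 libraries (24979 peaks). TKO lists were therefore not shorter than both day 0 lists. With these 4 libraries an effect of list length cannot be told apart from a true excess of falls or from the spread between the day 0 libraries. Falls outnumbered rises on 17 of 23 chromosomes, which argues against loss of 1 chromosome or arm as the source of the whole excess. A count by chromosome cannot exclude that lost arms or segments contribute. The share of day 0 regions lost in TKO ran from 2.29% on chromosome 19 to 22.6% on chromosome 4. On the 5 chromosomes with the most protein-coding genes per Mb (19, 17, 11, 16 and 22) the lower share was 30.5% (116 lower and 264 higher, 26.1% to 35.3%) against 68.3% on the others, and 20.7% and 18.7% of TKO peaks lay there against 16.3% and 16.8% in day 0 KMS11 and 18.0% to 19.1% in the 8 other KMS11 libraries, so a GC bias of libraries may contribute, but it was found from this same table, no GC content was computed, and it stays open. If TKO lacks NSD2, which the labels do not state, its lost regions would be called less often under NSD2LDD, and the change in KMS11 was -3.75 percentage points (exact permutation p = 0.40 ignoring day and 0.0556 within day, the lowest that 36 relabellings can give, so that p under 0.05 was out of reach) and over both lines -2.82, or -4.57 with lists of equal length (exact permutation p = 0.340 and 0.0170), the last 3 p values chosen after seeing the data, which leaves this open too.

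Regions lost in TKO were also called less often at day 10 than at day 4 under DMSO in KMS11 (80.7 ± 6.07% and 90.3 ± 1.10%, n = 2 each). Shorter lists at day 10 are argued against, since with lists of equal length the difference was -7.74 percentage points and both day 10 libraries lay below both of day 4. Kept regions of matched strength changed by -0.684, so the fall was not shared by all regions called at day 0. Kept regions were chosen as called in both TKO libraries as well, which makes them more steadily called. A fall of all less steadily called regions therefore stays open. Time in culture stays open and was not tested, and with 2 libraries against 2 the lowest exact p is 0.333.

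KMS11 regions called under NSD2LDD overlapped those called in TKO in the same direction 14 times and in opposite directions 1 time. Day 0 and DMSO KMS11 are the same line, so a region called in both can hardly rise in either comparison, nor an uncalled one fall. The low opposite count therefore cannot exclude regions that are easily called in any comparison. In KMS34 the 18 same-direction regions were 1.54 times the 11.7 if independent (95% Poisson interval 0.914 to 2.44, regions taken as independent). In KMS11 there were 14 where 0.934 were due if independent (8.20 to 25.2 times). TKO shares its baseline line with KMS11 alone, and 9835 regions were lower and 13862 higher in KMS34 at baseline. The ratios therefore cannot show whether a shared effect is weaker in KMS34. A shared effect of NSD2 loss may contribute, but the change over all regions lost in TKO (-3.75 percentage points in KMS11) does not decide it. Day 0 and DMSO libraries of KMS11 are separate, so the differences themselves share no library. The calls are still not independent, since both use 1 estimate of the spread of each region from all 22 libraries.

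Regions lost in TKO lay beside each other along the genome: 53.2% had a lost neighbour among the regions called in day 0 KMS11, against a mean of 30.6% and a highest value of 35.7% when lost regions were placed at random within class and chromosome (permutation p = 1e-05, the smallest that 100000 placements can give). The placements matched neither peak strength, distance to genes nor GC content. The lost share was 29.1% between genes and 37.1% more than 50 kb from a protein-coding gene. Differences of this kind along a chromosome can also bring lost regions together. The test therefore argues only against random placement within class and chromosome.

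Other splits of the same libraries were fitted with the day left out. Chance cannot be excluded for the regions changed by NSD2LDD in KMS11, where 14 of 35 splits gave as many (39 for the real split, highest other 315), and the highest was the split of day 4 from day 10, which points to a structure of the samples by day, while the fit with a mean for each day called 48. It cannot be excluded in KMS34 either (11 of 35, 98, highest other 249), nor for genes in KMS11 (8 of 35, 2, highest other 12) or in KMS34 (6 of 35, 4, highest other 21). For genes whose effect differs between lines the real split gave 0, so all 100 of 100 splits gave as many whatever the data (highest other 4), and this decides nothing. Chance is excluded for differences between the lines, where 1 of 100 splits, the real one, gave 23165 regions (highest other 10101) and 5935 genes (highest other 2335). In TKO the 3 splits are too few for a share under 0.05, with 2815 regions in the real split (1 as large, highest other 398) and 785 genes (1 as large, highest other 59).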
